A study of Mus musculus with 18 samples.

How the data were processed

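The deposited table holds 22787 mouse genes in 18 columns, 1 per library. Per the labels, 12 libraries are sorted granulocyte-monocyte progenitors (Raptor fl/fl, Raptor KO, Tsc2 fl/fl and Tsc2 KO, 3 each) and 6 are DR-ER-Hoxb8 cells differentiated for 3 days in DMSO, rapamycin or SL0101 (2 each). The authors' notes name BWA, TopHat2 2.0.10, Cufflinks 2.2.1 and Cuffnorm. The genome build is not given in the sources used here. The deposited values are signal units: the authors' fragment counts per gene divided by a size factor per library. Between 98.9% and 99.1% of the non-zero values of a library were whole multiples of 1 step (tolerance 0.01), and the size of that step gave the fragments per library. Fragments per library came to 2.48 to 3.52 M in progenitors and 2.31 to 3.30 M in Hoxb8 cells. The most abundant gene took 0.713% to 2.24% and 0.704% to 1.79% of a library. Of all genes, 5815 were at 0 in every library and 116 had values that point to fragments shared with other genes.

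Groups were taken from the sample titles, since 1 label field of the Tsc2 samples names Raptor. Progenitors and Hoxb8 cells were fitted separately in limma 3.58.1 under R 4.3.3, on log2 of the value plus 1, with 4 and 3 groups, moderated variances, an expression trend and robust estimation. Genes were tested if they reached a value of 1 in at least 3 progenitor libraries or at least 2 Hoxb8 libraries. The comparisons, 6 in all, were: each knockout against its fl/fl control, the difference between both knockout effects, each inhibitor against DMSO, and rapamycin against SL0101. P values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. Gene lists, 31 in all, were written before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The fry test asks whether the genes of a list move, on balance, 1 way, or in its mixed form whether they change in either direction, and neither form compares a list with other genes.

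The genes to be named were fixed by a rule written before the data were examined. It takes Rptor and Tsc2, and the 10 highest and 10 lowest log2 fold changes among genes that passed, had at least 10 normalized units per M in the higher group and had libraries that did not overlap. It adds up to 4 members that passed from each list with a camera adjusted p under 0.05 or at least 3 such members, and up to 3 members of the monocyte, neutrophil, sterol and glycolysis lists regardless of the test. The text names part of them, and says so where a gene falls outside the rule; a few genes that the rule names are not reported here. Overlaps of called genes were tested with Fisher's exact test. For the shared DMSO libraries, 100 draws of unchanged groups were simulated.

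The test was checked on simulated data with 200 planted genes per fold. In progenitors 1.5%, 47.5% and 98% of genes planted at 1.5, 2 and 4-fold were recovered, with 0, 6 and 6 false calls, and in Hoxb8 cells 2.5%, 53% and 100%, with 1, 2 and 10. Changes were planted only in genes with means well above the value of 1 needed for testing. Genes of similar mean were given the same spread. These rates therefore do not cover genes near 0. Of 2 planted lists camera called 2 in both fits with the preset correlation, and 2 in progenitors and 1 in Hoxb8 cells with an estimated correlation, with 0 of 40 unchanged lists. The simulated genes varied independently of each other. This check therefore cannot show false list calls that arise when the genes of a list vary together. Alternatives covered the expression trend, quantile normalization, the filter, the pseudocount, a replicate block, the libraries in the fit and leaving out each library. Tests for whole counts (DESeq2, or scaling by RLE, TMM or library totals in a count test) were not run, because not every value was a whole multiple of the step. Among the alternatives only limma with voom weights used the recovered fragments.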

Results

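RNA of 18 mouse samples was profiled by SmartSeq2 low-input sequencing. Of these, 12 were granulocyte-monocyte progenitors (GMPs), the bone marrow cells from which neutrophils and monocytes arise. They fell into 4 groups of 3 libraries: Raptor KO and Raptor fl/fl, Tsc2 KO and Tsc2 fl/fl. Raptor (gene Rptor) is the subunit that defines the kinase complex mTORC1, and Tsc2 belongs to the complex that holds mTORC1 inactive, so the knockouts are meant to remove and release mTORC1 activity, which was not measured here. Each GMP sample held 10000 cells, sorted from marrow stained with a lineage panel as positive for c-kit and FcγRII/III, low for CD34 and Ly6C, and negative for Sca-1, CD127 and CD135. The other 6 libraries came from DR-ER-Hoxb8 cells, a progenitor line held immature by estradiol-dependent Hoxb8. These were differentiated for 3 days without estradiol in DMSO, in rapamycin at 100 nM (an inhibitor of mTORC1) or in SL0101 at 10 nM (an inhibitor of the RSK kinases), with 2 libraries each. The SL0101 dose is as the labels give it and lies far below those usually used for this compound, and RSK activity was not measured. The deposited values are fragments per gene divided by a size factor per library, in signal units. The libraries held 2.48 to 3.52 M fragments in GMPs and 2.31 to 3.30 M in Hoxb8 cells, with 11854 to 12585 and 10871 to 11842 genes at a value of 1 or more. The labels do not say whether replicates were separate animals or cultures. With group means removed, Tsc2 fl/fl and Tsc2 KO libraries of replicates 1, 2 and 3 correlated at r = 0.217, 0.245 and -0.03. In the Raptor line these values were 0.026, 0.047 and 0.010. The main fit has no pairing, and the replicate block tried as an alternative is common to both lines. A pairing within the Tsc2 line alone was not tested. Genome positions are not given, since the build is not given in the sources used here. All adjusted p values are Benjamini-Hochberg values from limma for genes and from camera for gene lists. Fold changes are log2 changes of the value plus 1, which understate changes of genes near 0.

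The targeted genes came first. Tsc2 fell from 248 ± 18.0 in Tsc2 fl/fl to 95.1 ± 10.8 in Tsc2 KO (SD, n = 3 each; log2 fold change -1.38, limma adjusted p = 1.7e-04). Rptor was 84.5 ± 5.11 in Raptor fl/fl and 63.3 ± 5.61 in Raptor KO (n = 3 each), a log2 fold change of -0.41 that did not pass the test (adjusted p = 0.377), although every Raptor KO library was below every Raptor fl/fl library (chance gives 10% for 3 against 3 in either direction). Rptor in the Tsc2 line (log2 fold change -0.12, adjusted p = 0.807) and Tsc2 in the Raptor line (-0.26, adjusted p = 0.467) did not pass either. One label field of the Tsc2 samples names Raptor, and the Tsc2 values followed the sample titles used for grouping. Sex-linked transcripts showed that replicate 2 of Tsc2 fl/fl and replicate 2 of Tsc2 KO were male (summed signal of 4 Y-linked genes 384.9 and 317.7), while no other GMP library exceeded 0.8.

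**Figure D1:**
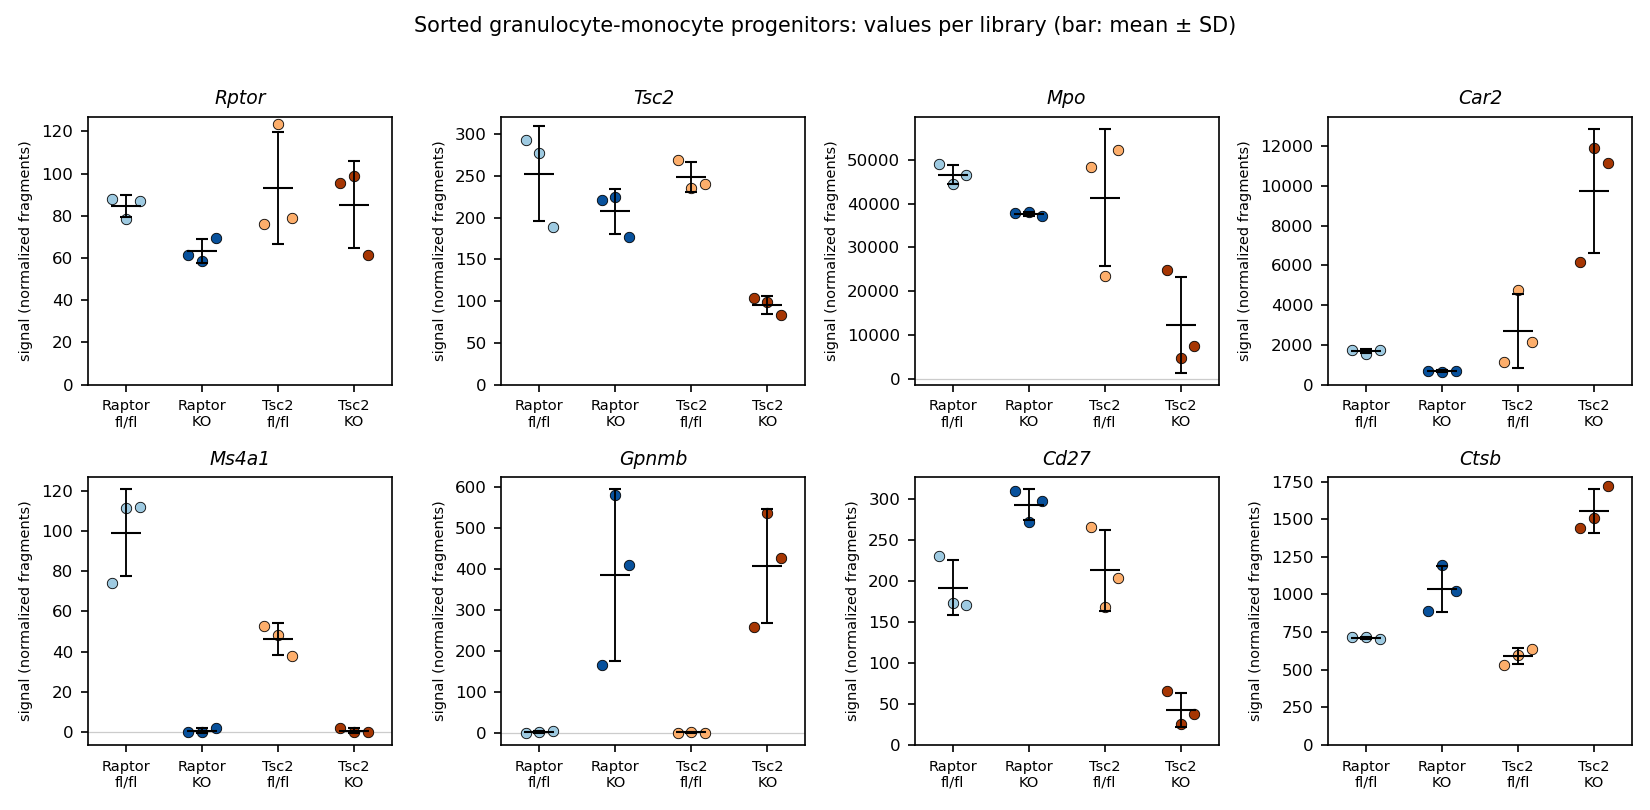
Signal (normalized fragments) of 8 genes in each GMP library, with the mean and SD of each group of 3 as bars. Tsc2 was lower in all 3 Tsc2 KO libraries, Gpnmb was near 0 in both fl/fl groups and at a mean of 384 and 407 in the knockouts, and Cd27 was lower in Tsc2 KO.

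The first comparison asks what the Raptor knockout changes in GMPs, where the fall of Rptor itself did not pass the test. As lists, erythroid and megakaryocyte genes (9 of 33 passed), lymphoid genes (10 of 30) and genes of respiration (18 of 72) were lower in Raptor KO, and lysosome genes (5 of 57) were higher. These are camera calls at a preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.221). The B cell gene Ms4a1 fell from 99.2 ± 21.6 to 0.626 ± 1.08 and the beta globin gene Hbb-b2 by 3.82 on the log2 scale. The fatty acid desaturase Scd1 fell from 47.1 ± 6.58 to 0.236 ± 0.408. Gpnmb, a glycoprotein of lysosome-rich phagocytes, rose from 1.87 ± 2.05 to 384 ± 209, and Cd33, a myeloid surface lectin, from 8.15 ± 5.29 to 144 ± 7.27 (SD, n = 3 each). With voom weights Gpnmb did not pass (adjusted p = 0.0682). In all, 522 of 13237 genes tested passed, 202 higher and 320 lower, and 293 of them changed at least 2-fold.

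Oxidative phosphorylation was the list with the smallest p in Raptor KO. Of its 72 nuclear genes, 18 fell and none rose (46 fell adjusted over the list alone; median log2 fold change -0.42, camera adjusted p = 1.6e-22). Ndufb7 of complex I fell from 398 ± 28.1 to 211 ± 44.9, and Taldo1, of the pentose phosphate pathway, from 1545 ± 52.1 to 954 ± 37.8 (limma adjusted p = 0.0024 and 0.001, n = 3). Cell cycle genes were lower: 5 of 37 S phase genes (14 adjusted over the list alone, with 1 higher) and 2 of 34 mitosis genes (3 adjusted over the list alone) fell. Their camera adjusted p were 3.7e-10 and 8.3e-06. Examples were Gmnn, which restrains relicensing of replication origins, and the DNA ligase Lig1, with log2 fold changes of -0.77 and -0.82. Sterol biosynthesis was lower as a list (median log2 fold change -0.47, camera adjusted p = 6.4e-04): of 25 genes 2 fell and 1, Hmgcs1, rose (1.02), also when adjusted over the list alone. None of these lists passed with an estimated correlation: adjusted p = 0.291 for mitosis and 0.221 for the others with an estimated correlation. In the same comparison, the list named mitochondrially encoded and nuclear-retained RNAs was called higher. Of 4 genes tested 2 rose, also adjusted over the list alone (median 0.86, camera adjusted p = 0.0057, adjusted p = 0.221 with an estimated correlation). The difference from Tsc2 KO passed as well (1 of 4 higher, 2 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.239 with an estimated correlation). Only 5 of the 31 symbols of this list were in the data, so most of its mitochondrial transcripts were absent. The sex-linked Xist was among the 5, at 1.7 in Tsc2 fl/fl replicate 2 and 1.4 in Tsc2 KO replicate 2, the male libraries. The list is thus a weak measure of RNA quality. Whether RNA quality moved other lists of Raptor KO was not tested.

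Several lineage lists were lower in Raptor KO. Among 33 erythroid and megakaryocyte genes, 9 fell (16 adjusted over the list alone, with 1 higher; median log2 fold change -1.24, camera adjusted p = 1.0e-14), among them Hbb-b1, part of whose fragments are shared with other genes (-3.61; adjusted p = 0.0619 with voom weights), the haem synthesis gene Alas2 (-2.83) and the platelet factor Pf4 (-2.65). Among 30 lymphoid genes, 10 fell (15 adjusted over the list alone; median -1.62, camera adjusted p = 1.4e-09). They included Cd79a at 221 ± 32.7 and 18.5 ± 7.24, and Ccr7, Cd22 and Vpreb3, with log2 fold changes between -4.49 and -3.56. Of 30 secondary granule and maturation genes of neutrophils, 4 fell and 1 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0099). Fcnb, a ficolin of granulocyte granules, fell by 3.30 on the log2 scale. The list call was lost without Raptor fl/fl replicate 3 (adjusted p = 0.112) or without Raptor KO replicate 1 (0.113). Of 20 primary granule genes none passed over all genes or rose adjusted over the list alone, where 1 fell (camera adjusted p = 0.134), and 3 fell among 38 interferon response genes (7 adjusted over the list alone, camera adjusted p = 5.0e-04), such as Ifi27l2a (-3.67). The tests gave adjusted p = 0.561 with an estimated correlation for secondary granules, 0.78 for primary granules and 0.221 for the erythroid, lymphoid and interferon lists.

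Among the genes that rose in Raptor KO, 5 of 57 were of lysosome and autophagy (9 adjusted over the list alone, camera adjusted p = 0.0031), among them Psap, a precursor of lysosomal cofactors, from 325 ± 3.66 to 775 ± 177. The cathepsin Ctss, of the monocyte and macrophage list, rose from 88.5 ± 12.6 to 300.2 ± 66.9. That list as a whole did not pass (6 of 46 rose, 11 adjusted over the list alone with 2 lower, camera adjusted p = 0.131). In the list of ERK and RSK output, 3 of 21 rose (5 adjusted over the list alone, camera adjusted p = 0.002): Egr1, an immediate early gene, rose from 484 to 1032 ± 90.5, while Rps6ka3 (log2 fold change 1.33) encodes the kinase RSK2 itself. Of 44 ribosome biogenesis and Myc target genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.001), Myc by 0.71. Of 35 myeloid transcription factors, 4 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0066): Junb rose by 0.96 and Irf4 fell by 2.43 on the log2 scale. Of 27 cytokine receptors 2 rose, as did Socs3, an inhibitor of cytokine signals, from 12.3 ± 0.937 to 58.5 ± 7.82 (2 receptors adjusted over the list alone, camera adjusted p = 0.001). The stem and early progenitor list was called higher (3 of 28 rose, 4 adjusted over the list alone, camera adjusted p = 0.0266). Without Raptor KO replicate 3 that call was lost (adjusted p = 0.0652). These lists had adjusted p = 0.291 with an estimated correlation for lysosome and ribosome biogenesis, 0.368 for cytokine receptors, 0.653 for monocyte genes and 0.221 for the ERK, transcription factor and stem lists.

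The call of cytosolic ribosomal protein genes in Raptor KO depended on scaling and on single libraries. Of 71, 6 rose (9 adjusted over the list alone, camera adjusted p = 0.0037; adjusted p = 0.713 with an estimated correlation), with Rplp0 at a log2 fold change of 0.41. The call was lost under quantile normalization (0.127), where none passed, and without Raptor fl/fl replicate 2 (0.119), and without Raptor KO replicate 1 the list's median was -0.05 (0.467). The number of genes called in Raptor KO fell to 146 without Raptor KO replicate 2, to 147 without replicate 3, and to 194, 228 and 253 without Raptor fl/fl replicates 1, 2 and 3. Irf4 lost its call without Raptor KO replicate 2 (limma adjusted p = 0.056), and Hmgcs1 without Raptor fl/fl replicates 1 or 2 or Raptor KO replicates 2 or 3 (highest adjusted p = 0.0882).

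The 2nd comparison asks what loss of Tsc2 changes in GMPs. As lists, primary granule (10 of 20 passed), stem cell (17 of 28) and lymphoid genes (13 of 30) were lower in Tsc2 KO, while lysosome (16 of 57), amino acid (15 of 40) and mitosis genes (15 of 34) were higher. Among these lists only the stem cell list also passed in camera with an estimated correlation (adjusted p = 0.0317, 0.0786 or more for the others). The complement gene C1qb rose from 1.47 ± 1.79 to 73.5 ± 25.4, Gpnmb from 0.564 ± 0.977 to 407 ± 139 and the galectin Lgals3 from 13.7 ± 7.57 to 186 ± 25.1. Ifitm1, a membrane protein of early progenitors and interferon responses, fell from 308 ± 69.4 to 24.3 ± 3.15 (SD, n = 3 each). Of 13237 genes, 1638 passed, 696 higher and 942 lower, and 1020 changed at least 2-fold.

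In the primary granule and granulocyte progenitor list, 10 of 20 genes fell in Tsc2 KO and none rose (17 fell adjusted over the list alone; median log2 fold change -1.78, camera adjusted p = 8.4e-14). Trem3 fell from 102 ± 54.4 to 14.1 ± 12.3 and Alas1 from 574 ± 108 to 223 ± 118. With only the groups compared Alas1 did not pass (limma adjusted p = 0.0562). Mpo (myeloperoxidase), chosen after its values were seen, was 48343, 23511 and 52221 in the Tsc2 fl/fl libraries and 24793, 4820 and 7520 in Tsc2 KO (log2 fold change -2.02, adjusted p = 0.0515). It passed without Tsc2 fl/fl replicate 2 (0.033) or Tsc2 KO replicate 1 (0.0013) and, at 0.0107 to 0.0487, with a filter at 5 CPM, a replicate block, a common total, voom or a sex term. Replicate 2 of Tsc2 fl/fl, a male library, and replicate 1 of Tsc2 KO thus lay close together. Those 7 settings were the only ones in which Mpo passed, of 6 fits without 1 library and 11 other settings. Without 1 library its log2 fold change ranged from -2.70 to -1.51, with a limma adjusted p of up to 0.172. Stem and early progenitor genes fell in 17 of 28 cases (19 adjusted over the list alone with 1 higher; median -1.27, camera adjusted p = 2.3e-08). Cd27 fell from 213 ± 49.5 to 43.0 ± 20.6 and Meis1 from 94.7 ± 6.64 to 29.6 ± 6.09. Myeloid transcription factors fell in 13 of 35 cases and rose in 1 (16 and 2 adjusted over the list alone, camera adjusted p = 9.7e-05). Spi1, which encodes the myeloid regulator PU.1, fell from 363 ± 102 to 120 ± 26.0, Irf4 by 3.16 and Stat3 by 1.20 on the log2 scale. Lymphoid genes fell in 13 of 30 cases and rose in 1 (18 and 1 adjusted over the list alone; median -1.84, camera adjusted p = 1.6e-09), among them Cd79a, Ms4a1 and the B cell factor Ebf1 with log2 fold changes of -5.12, -5.02 and -4.26. The stem list passed also with an estimated correlation (adjusted p = 0.0317), and the others did not: adjusted p = 0.182 for primary granules, 0.119 for transcription factors and 0.155 for lymphoid genes with an estimated correlation.

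Erythroid and megakaryocyte genes went both ways in Tsc2 KO: 11 of 33 rose and 5 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.0023; adjusted p = 0.498 with an estimated correlation). The platelet and megakaryocyte genes Pf4 and Itga2b fell by 1.99 and 1.47 on the log2 scale. The erythroid carbonic anhydrase gene Car2, chosen after its values were seen, rose from 2691 ± 1867 to 9742 ± 3110.5 (limma adjusted p = 0.0231). The list call was lost without Tsc2 fl/fl replicate 1 (adjusted p = 0.0517). The same libraries that were low in Mpo were high in Car2, at 1158, 4770 and 2143 in Tsc2 fl/fl and 6178, 11910 and 11138 in Tsc2 KO.

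Lysosome and autophagy genes rose in 16 of 57 cases and fell in 2 (24 and 3 adjusted over the list alone, camera adjusted p = 1.2e-09). The cathepsins Ctsb, Ctsd and Ctsl rose from 591 ± 54.2 to 1556 ± 145, from 910.1 ± 48.1 to 1940.0 ± 184 and from 132 ± 32.7 to 532 ± 163. Amino acid and one-carbon genes rose in 15 of 40 cases and fell in 1 (21 and 1 adjusted over the list alone, camera adjusted p = 2.0e-08). Asparagine synthetase, Asns, rose from 308 ± 131 to 998 ± 285, Aldh18a1 of proline synthesis by a log2 fold change of 0.95 and the mTORC1 substrate gene Eif4ebp1 by 0.96. Lipid genes were higher as lists: 4 of 25 sterol genes (6 adjusted over the list alone, camera adjusted p = 3.7e-05) and 7 of 16 fatty acid genes (7 adjusted over the list alone, 0.0053) rose. The regulators Insig1 and Srebf1 had log2 fold changes of 0.99 and 0.80. Mitosis genes rose in 15 of 34 cases (26 adjusted over the list alone, camera adjusted p = 8.7e-12), with Ube2c from 442 ± 96.5 to 805 ± 128. S phase genes rose in 5 of 37 cases (6 adjusted over the list alone, 6.4e-05) and oxidative phosphorylation genes in 9 of 72 (9 adjusted over the list alone, 2.0e-07), such as Fen1 and Atp5b at log2 fold changes of 0.73 and 0.49. With only the groups compared Fen1 did not pass (limma adjusted p = 0.0679). These higher lists had adjusted p = 0.0843 with an estimated correlation for lysosome and sterol genes, 0.0786 for amino acid genes, 0.147 for fatty acid and mitosis genes, 0.409 for S phase and 0.498 for oxidative phosphorylation.

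The list of FOXO targets and PI3K feedback and that of ERK and RSK output were called lower in Tsc2 KO at the preset correlation only. Of 23 FOXO and PI3K feedback genes, 7 fell (9 adjusted over the list alone with 1 higher, camera adjusted p = 0.002; adjusted p = 0.116 with an estimated correlation). The cyclin gene Ccnd2 fell by 1.26 on the log2 scale. Outside this list, the hypoxia gene Ndrg1 fell by 1.52 and Myc fell from 785 ± 59.2 to 433 ± 73.5. Of 21 ERK and RSK output genes, 5 fell (8 adjusted over the list alone with 1 higher, camera adjusted p = 0.0229; adjusted p = 0.296 with an estimated correlation). That call was lost without Tsc2 fl/fl replicate 3 (adjusted p = 0.0592), without Tsc2 KO replicate 2 (0.0646) and without both male libraries (0.0611). Of 27 cytokine receptors, 5 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.0018; adjusted p = 0.45 with an estimated correlation). Among 46 monocyte and macrophage genes 8 rose and 4 fell (10 and 5 adjusted over the list alone), a list that did not pass (camera adjusted p = 0.491) and whose median of -0.26 and mean of 0.22 differed in sign. Lgmn, a lysosomal protease of macrophages, and Ctss rose by log2 fold changes of 3.11 and 1.85. Of 30 secondary granule genes 5 fell, also adjusted over the list alone, while the list's median was 0.40 and it did not pass (0.766). Among 22 glycolysis genes 1 rose and 1 fell (1 and 5 adjusted over the list alone, 0.714).

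The number of genes called in Tsc2 KO fell to 601, 662, 705 and 860 without Tsc2 KO replicate 3, Tsc2 KO replicate 2, Tsc2 fl/fl replicate 1 and Tsc2 fl/fl replicate 3, and rose to 2498 without Tsc2 KO replicate 1. Insig1 lost its call in 2 of the 6 such fits (without Tsc2 fl/fl replicate 1 and Tsc2 KO replicate 2) and Srebf1 in 3 (also without Tsc2 KO replicate 3). Their log2 fold changes in the fits that lost the call were 0.79 and 0.88, and 0.51, 0.75 and 0.76. Both also lost it without an expression trend (adjusted p = 0.0526 and 0.0737) and with only the groups compared (0.0568 and 0.0836), and Insig1 without the male libraries (0.0871). Car2 lost its call without Tsc2 fl/fl replicate 3, Tsc2 KO replicate 2 or Tsc2 KO replicate 3 (log2 fold changes of 1.99, 1.86 and 1.91, highest limma adjusted p = 0.0988) and with only the groups compared (0.0942).

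The 3rd comparison tests whether the 2 knockouts had different effects, as the Raptor KO effect minus the Tsc2 KO effect. For 1646 of 13237 genes it passed, 793 higher and 853 lower. Ifitm1, Klk8, Cd27 and Meis1 had positive differences of 5.16, 4.58, 2.98 and 2.28 on the log2 scale. These 4 were lower in Tsc2 KO, and Ifitm1 was also higher in Raptor KO (1.56), where the rises of the other 3 did not pass. Scd1 had the most negative difference of the genes chosen by rank, -7.23: it was lower in Raptor KO and at 31.4 ± 19.9 and 105 ± 34.7 in Tsc2 fl/fl and Tsc2 KO (SD, n = 3). Myc differed by 1.58, the tyrosine kinase receptor gene Flt3 by 2.33 and the death inhibitor Bcl2 by 2.46. Tsc2 itself differed by 1.11 (limma adjusted p = 0.0098).

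Of 31 lists 21 passed for the difference, 9 positive and 12 negative; progenitor lists were among the positive ones, and metabolic, cycle and erythroid lists among the negative ones. The stem and early progenitor list passed with both correlations (13 of 28 higher, 19 adjusted over the list alone; camera adjusted p = 1.7e-08; adjusted p = 0.0291 with an estimated correlation). Myeloid transcription factors (10 of 35 higher and 1 lower; 14 and 1 adjusted over the list alone) and primary granule genes (5 of 20 higher; 7 adjusted over the list alone) had camera adjusted p of 4.0e-06 and 1.0e-06. Lower differences were found for 35 of 72 oxidative phosphorylation genes (51 adjusted over the list alone, camera adjusted p = 2.6e-21), 17 of 34 mitosis genes (27 adjusted over the list alone, 1.1e-13) and 16 of 37 S phase genes with 1 higher (23 and 1 adjusted over the list alone, 9.8e-11). Erythroid and megakaryocyte genes differed negatively in 15 of 33 cases and positively in 2 (19 and 2 adjusted over the list alone, 3.7e-11), amino acid genes in 12 of 40 and 1 (15 and 1 adjusted over the list alone, 5.9e-07) and sterol genes in 8 of 25 (10 adjusted over the list alone, 5.2e-07). Rrm2, Cenpa, Ndufb9, Asns, Mthfd2 and Fdps were examples, at -1.47, -1.37, -1.06, -2.37, -2.37 and -1.18. Differences had adjusted p = 0.087 with an estimated correlation for transcription factors and amino acid genes, 0.327 for primary granules, 0.21 for oxidative phosphorylation, 0.156 for mitosis, 0.172 for S phase and erythroid genes, and 0.0604 for sterol genes. For the lymphoid list, lower in both lines, the difference did not pass (1 of 30 higher, none adjusted over the list alone; camera adjusted p = 0.542). Both knockouts called 141 genes (64.6 by chance), 60 of them in the same direction (20 higher, 40 lower; Fisher's exact test of overlap, two-sided p = 2.9e-20). The others moved apart, 19 higher in Raptor KO and lower in Tsc2 KO and 62 the reverse (14.4 and 16.8 by chance). The chance counts and the overlap p assume independent comparisons, while both take the spread of each gene from the same fit. The directions were not associated (Fisher's exact p = 0.343), and the Pearson r over all genes was -0.02. The number of genes with a difference was 897, 931, 947, 1004, 1046 and 1085 without Tsc2 KO replicate 2, Tsc2 KO replicate 3, Raptor KO replicate 2, Raptor KO replicate 3, Tsc2 fl/fl replicate 1 and Raptor fl/fl replicate 1, and 2519 without Tsc2 KO replicate 1.

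**Figure D2:**
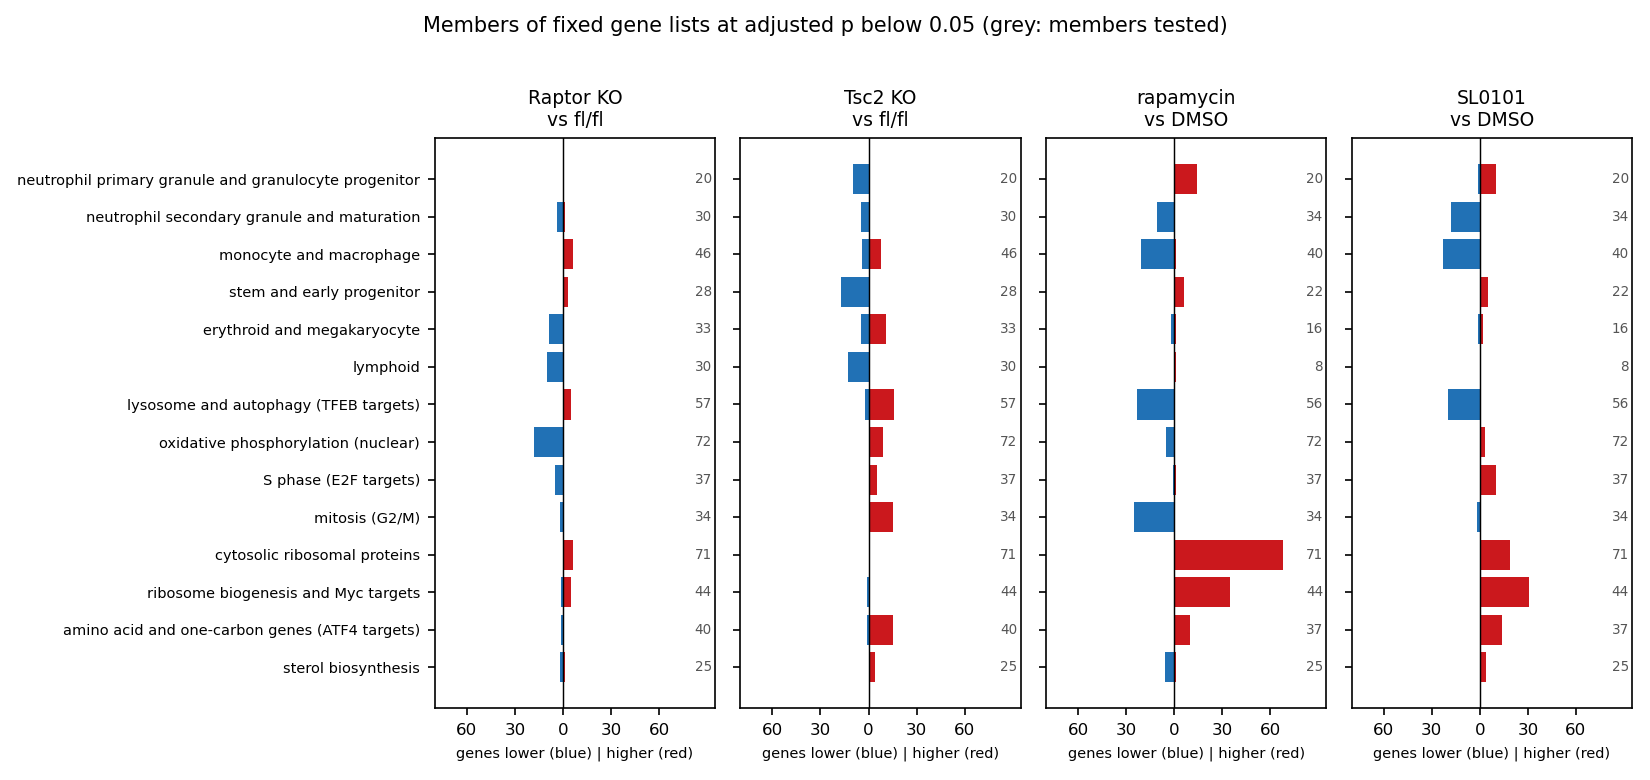
Number of members of 14 of the 31 gene lists that passed at adjusted p below 0.05 in 4 of the 6 comparisons, lower (blue, left) or higher (red, right), with the number tested in grey. Ribosomal protein genes were higher with rapamycin in 68 of 71 cases and monocyte genes lower with both inhibitors, while primary granule genes were lower in Tsc2 KO (10 of 20) and higher with rapamycin (14 of 20).

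The 4th comparison asks how rapamycin changes the differentiation of Hoxb8 progenitors. After 3 days, lists of primary granule (14 of 20 passed), ribosomal protein (68 of 71) and early progenitor genes (6 of 22) were higher in rapamycin than in DMSO. Lists of monocyte (21 of 40), lysosome (23 of 56), secondary granule (11 of 34) and mitosis genes (25 of 34) were lower. None of them passed in camera with an estimated correlation (lowest adjusted p = 0.16). Mpo rose from 6469.7 ± 233 to 41158 ± 2649 and the neutrophil elastase gene Elane from 1132 ± 32.2 to 4194 ± 909. Myc rose from 79.5 ± 16.1 to 514 ± 77.8. The macrophage receptor gene Trem2 fell from 113 ± 19.4 to 3.97 ± 0.865, the cathepsin gene Ctss from 287 ± 39.2 to 20.1 ± 7.85 and the neutrophil surface gene Cd177 from 255 ± 23.2 to 20.6 ± 0.652 (SD, n = 2 each). Of 11804 genes 1386 passed, 637 higher and 749 lower, and 617 changed at least 2-fold.

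Cytosolic ribosomal protein genes rose in 68 of 71 cases with rapamycin (69 adjusted over the list alone; median log2 fold change 0.97, camera adjusted p = 1.5e-52). Rpl12 rose from 1604 ± 181 to 4268 ± 565. Ribosome biogenesis and Myc target genes rose in 35 of 44 cases (36 adjusted over the list alone, 9.6e-24), among them Ppan and Npm1 at log2 fold changes of 1.78 and 1.15. Primary granule genes rose in 14 of 20 cases (16 adjusted over the list alone, 1.9e-16), with Prtn3 and Ctsg at 1.77 and 1.93. Stem and early progenitor genes rose in 6 of 22 cases (11 adjusted over the list alone, 5.2e-07), with Kit, Myb and Cdk6 at 1.15, 1.49 and 1.14. Amino acid and one-carbon genes rose in 10 of 37 cases (13 adjusted over the list alone with 1 lower, 5.2e-05), Psat1 of serine synthesis by 0.86. Of 17 ERK and RSK output genes 4 rose (5 adjusted over the list alone, 0.008); Dusp6, a phosphatase induced by ERK, rose by 1.62. Higher lists had adjusted p = 0.16 with an estimated correlation for ribosome biogenesis and stem genes and 0.202 for the ribosomal protein, primary granule, amino acid and ERK lists.

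Monocyte and macrophage genes fell in 21 of 40 cases with rapamycin and rose in 1 (26 and 2 adjusted over the list alone; median log2 fold change -1.36, camera adjusted p = 1.8e-15). Fn1 fell from 597 ± 107 to 105 ± 20.1, Pld4 from 547 ± 129 to 64.3 ± 2.32 and the chemokine receptor gene Cx3cr1 from 267 ± 2.75 to 59.6 ± 27.2. Lysosome and autophagy genes fell in 23 of 56 cases (30 adjusted over the list alone, 1.8e-11), with Psap from 3372 ± 187 to 821 ± 137. Secondary granule and maturation genes fell in 11 of 34 cases (16 adjusted over the list alone, 3.3e-08); Chil1 fell by 1.75 on the log2 scale. Mitosis genes fell in 25 of 34 cases (31 adjusted over the list alone, 1.3e-18), among them Nusap1, Plk1 and Ccna2 by 0.87, 1.05 and 0.90 on the log2 scale. Sterol genes fell in 6 of 25 cases and rose in 1 (9 and 1 adjusted over the list alone, 2.6e-05): Hmgcs1 fell by 0.81 on the log2 scale. Cytokine receptor genes fell in 6 of 24 cases and rose in 1 (9 and 1 adjusted over the list alone, 0.0012). Lower lists had adjusted p = 0.269 with an estimated correlation for secondary granules, 0.16 for sterol genes and 0.202 for the monocyte, lysosome, mitosis and receptor lists.

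Fatty acid synthesis (3 of 15 fell, also adjusted over the list alone, camera adjusted p = 0.0396) and reactive oxygen genes (5 of 25 fell, also adjusted over the list alone, 0.0396) had weaker calls with rapamycin. The desaturase gene Fads2 fell from 75.3 ± 0.817 to 13.1 ± 0.429, and Cybb, the catalytic subunit of the phagocyte oxidase, from 2333 ± 235 to 1012 ± 73.0. Both list calls were lost without DMSO replicate 2 (adjusted p = 0.0747 and 0.16), the first also without rapamycin replicate 2 (0.0785) and under quantile normalization (0.122), the last also without rapamycin replicate 1 (0.111). With an estimated correlation the adjusted p = 0.269 and 0.258. Of 21 glycolysis genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.908). Rptor was 106 ± 6.03 in DMSO and 65.8 ± 3.59 in rapamycin (limma adjusted p = 0.0533), and the fall passed with quantile normalization, a filter at 5 CPM, a replicate block or a common total (0.0306 to 0.0495). The number of genes called fell to 568 and 540 without DMSO replicates 1 and 2.

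**Figure D3:**
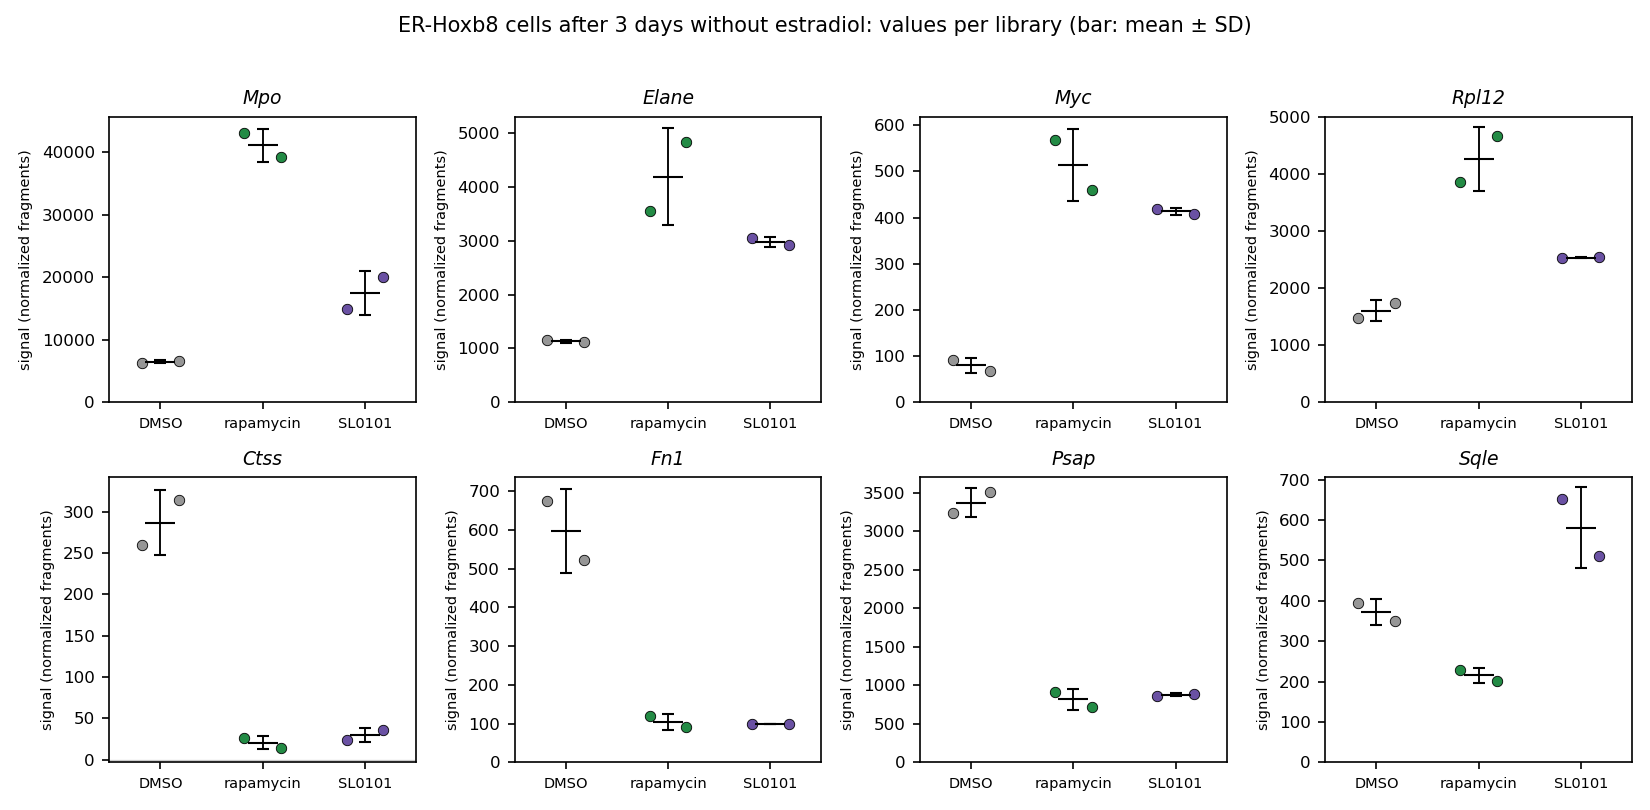
Signal (normalized fragments) of 8 genes in each Hoxb8 library, with the mean and SD of each group of 2 as bars. Mpo, Elane and Myc were higher and Ctss, Fn1 and Psap lower with both inhibitors, and Sqle was at 372 ± 31.7 in DMSO, 215 ± 18.0 in rapamycin and 581 ± 101 in SL0101.

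The 5th comparison asks the same of SL0101. Like rapamycin, SL0101 gave higher lists of primary granule (10 of 20 passed) and ribosome biogenesis genes (31 of 44) and lower lists of monocyte (23 of 40), lysosome (20 of 56) and secondary granule genes (18 of 34) than DMSO. Sterol (4 of 25), fatty acid (4 of 15) and S phase genes (10 of 37) were higher as lists. None of them passed in camera with an estimated correlation (lowest adjusted p = 0.153). Myc rose from 79.5 ± 16.1 to 414 ± 7.41, Mpo from 6469.7 ± 233 to 17468 ± 3576 and Elane from 1132 ± 32.2 to 2983 ± 93.4. Ctss fell from 287 ± 39.2 to 29.6 ± 8.49, the chemokine receptor gene Ccr2 from 152 ± 39.0 to 20.4 ± 6.55 and the collagenase gene Mmp8 from 277 ± 15.9 to 50.9 ± 19.5 (SD, n = 2 each). Of 11804 genes 1284 passed, 601 higher and 683 lower, and 555 changed at least 2-fold. Without an expression trend 87 passed, 12 higher and 75 lower, and Mpo, Elane and Mmp8 were not among them (adjusted p = 0.0667, 0.0688 and 0.0547).

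Ribosome biogenesis and Myc target genes rose in 31 of 44 cases with SL0101 (36 adjusted over the list alone, camera adjusted p = 3.1e-25), with Rrs1 and Nop58 at log2 fold changes of 1.61 and 1.21. Ribosomal protein genes rose in 19 of 71 cases (35 adjusted over the list alone, 8.7e-12). Amino acid and one-carbon genes rose in 14 of 37 cases (15 adjusted over the list alone, 7.4e-08), the glutamine carrier gene Slc1a5 by 1.25. Primary granule genes rose in 10 of 20 cases and fell in 1 (11 and 2 adjusted over the list alone, 1.9e-05). S phase genes rose in 10 of 37 cases (15 adjusted over the list alone, 6.4e-07), with Mcm2 from 603 ± 0.926 to 1104 ± 52.0. Sterol genes rose in 4 of 25 cases (5 adjusted over the list alone, 6.5e-05) and fatty acid genes in 4 of 15 (5 adjusted over the list alone, 0.0022), Insig1 from 617 ± 24.3 to 1090.5 ± 73.0. With an estimated correlation the adjusted p = 0.153 for ribosome biogenesis, 0.461 for ribosomal proteins, 0.26 for primary granules, 0.271 for S phase, and 0.239 for the amino acid, sterol and fatty acid lists.

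Monocyte and macrophage genes fell in 23 of 40 cases with SL0101 and rose in 1 (29 and 1 adjusted over the list alone; median log2 fold change -1.47, camera adjusted p = 2.1e-20), with Fn1 from 597 ± 107 to 99.1 ± 0.841 and Mpeg1 from 745 ± 174 to 147 ± 12.7. Secondary granule genes fell in 18 of 34 cases (20 adjusted over the list alone, 3.5e-15), with Ltf, the lactoferrin gene, from 11433 ± 659 to 4159.6 ± 1446. Lysosome and autophagy genes fell in 20 of 56 cases (26 adjusted over the list alone with 2 higher, 1.6e-08), Psap by 1.94 on the log2 scale. Cytokine receptor genes fell in 9 of 24 cases and rose in 1 (11 and 1 adjusted over the list alone, 4.4e-05), and interferon response genes in 4 of 28 and 1 (5 and 1 adjusted over the list alone, 0.0036). With an estimated correlation the adjusted p = 0.26 for the interferon list and 0.239 for the other 4. Of 21 glycolysis genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.971). The number of genes called fell to 438, 323 and 439 without DMSO replicate 1, DMSO replicate 2 and SL0101 replicate 1.

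The 6th comparison sets rapamycin against SL0101 directly. The compounds were given at 100 nM and 10 nM, so the doses differ. Lists of lipid synthesis, mitosis and S phase genes were lower in rapamycin than in SL0101 at the preset correlation, and those of ribosomal protein and primary granule genes were higher. Sqle and Insig1 of the sterol pathway were 215 ± 18.0 and 403 ± 2.32 in rapamycin, against 581 ± 101 and 1090.5 ± 73.0 in SL0101. Mpo was 41158 ± 2649 against 17468 ± 3576, Mmp8 295 ± 43.1 against 50.9 ± 19.5, and the serpin gene Serpinb10 427 ± 104 against 73.4 ± 18.4 (SD, n = 2 each). Of 11804 genes 1047 passed, 523 higher and 524 lower in rapamycin (440 and 699 with columns scaled to a common total), and 279 differed at least 2-fold. Ribosomal protein genes were higher in 55 of 71 cases (65 adjusted over the list alone, camera adjusted p = 3.5e-32), with Rpl7 and Rps25 at log2 fold changes of 1.05 and 1.00. Primary granule genes were higher in 11 of 20 cases (13 adjusted over the list alone, 2.5e-08) and stem genes in 4 of 22 (6 adjusted over the list alone, 1.6e-04), such as Myb at 0.93. Mitosis genes were lower in 20 of 34 cases (25 adjusted over the list alone, 1.7e-16), sterol genes in 13 of 25 (20 adjusted over the list alone, 1.5e-14), S phase genes in 12 of 37 (18 adjusted over the list alone, 1.2e-09) and fatty acid genes in 8 of 15 (8 adjusted over the list alone, 2.5e-07). Ccna2, Hmgcs1, Rrm2 and Fads2 were at -1.19, -1.06, -0.88 and -2.80. Of 4 genes tested from the list of mitochondrial and nuclear-retained RNAs 2 were higher, also adjusted over the list alone (0.0067), and the nuclear Malat1 was at 1.22. Most mitochondrial transcripts of that list were absent from the data. With an estimated correlation the adjusted p = 0.0929 for sterol genes, 0.22 for stem and fatty acid genes and 0.357 for the others. The number of genes called fell to 128 without SL0101 replicate 1 and to 695 without rapamycin replicate 2, and limma without an expression trend in the prior variance called 0 genes, with 2787 at an unadjusted p under 0.05 in the fit with the trend.

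Rapamycin and SL0101 called 604 genes in common, and 598 of them moved the same way (296 higher, 302 lower; 32.4 and 43.3 by chance; Fisher's exact test of overlap, two-sided p = 9.5e-262). The chance counts and this p assume independent comparisons, while both use the same DMSO libraries. Fold changes correlated across the 11804 genes at Pearson r = 0.618, where unchanged groups simulated against the same DMSO libraries gave a mean of 0.498. The covariance was 0.288, against a highest simulated value of 0.102. The share of all genes with the same sign, 65.9%, did not exceed the simulated mean of 66.6% (highest 67.7%). Raptor KO and rapamycin, which share no libraries, called 93 genes in common among 11334 (48.1 by chance). Of these, 67 moved the same way (27 higher, 40 lower; 8.41 and 16.0 by chance; Fisher's exact test of overlap, two-sided p = 1.8e-10). Across genes their fold changes had a Pearson r of 0.079, and genes are not independent replicates. Myc and Rplp0 were higher in both, and Psap moved in opposite directions. In Raptor KO neither Myc nor Rplp0 passed without an expression trend (adjusted p = 0.0672 and 0.155), nor did Rplp0 under quantile normalization (0.187).

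**Figure D4:**
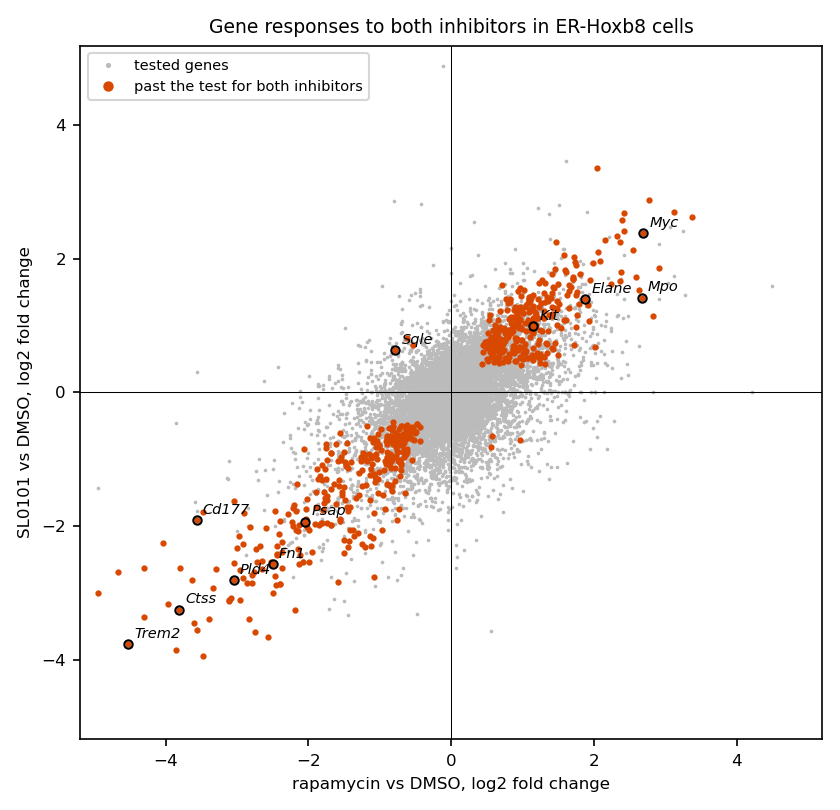
Log2 fold changes against DMSO of 11804 genes with rapamycin (x) and SL0101 (y); genes that passed for both inhibitors are orange and 11 named genes are circled. Most orange points lie in the lower left and upper right quadrants (302 and 296).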

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

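Of the tests below, those of other splits of the libraries were set before their results were seen, that of sex leaves out the male libraries, a step chosen after seeing the data but before the medians given here were known, and the tests of cell types in the sort, B cells, scaling and shared DMSO libraries were chosen only after the results were seen. The effects of the Raptor and the Tsc2 knockout in progenitors differed for 1646 genes by a test of the difference itself (limma). Of 100 splits of the libraries within each line, 1, the real one, gave as many genes, and the highest other split gave 760. For gene lists the real split gave 21 and the highest other 20, again with 1 of 100 as large. No other split drawn reached the real gene count. The splits regroup both lines, so they ask whether neither knockout has an effect, not whether the effects are equal. An effect in 1 line may be enough, as the split with 760 genes kept the real Raptor groups. The split with both real groupings and the Tsc2 direction reversed was not drawn. For lists the margin was 1 list, and the 6 other splits drawn with the real Tsc2 groups in their real direction gave 18 to 20. Splits with the direction of those groups reversed gave 15 to 17. The list count thus does not show that both lines contribute. With 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. In Raptor KO, 1 of the 10 gave as many genes (522, highest other 0), 1 as many lists (19, highest other 12) and 1 as many genes shared with rapamycin (67, highest other 0). The other Raptor splits called 0 genes, so their overlap with rapamycin had to be 0 and is no separate test. They still called 3 to 12 lists at the preset correlation. In Tsc2 KO, 1 gave as many genes (1638, highest other 809) and 1 as many lists (19, highest other 18). The other Tsc2 splits called 8 to 18 lists at the preset correlation, so the list count barely set the real grouping apart. The split with 809 genes set Tsc2 fl/fl replicates 1 and 3 and Tsc2 KO replicate 1 against the other 3 libraries, which points to a structure of the samples.

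In Tsc2 KO, primary granule genes were lower beside 13 higher early erythroid genes, a part of the erythroid and megakaryocyte list picked after the values were seen. Sex is argued against as the cause by the design, since Tsc2 fl/fl and Tsc2 KO each held 1 male library. Leaving both out could thus change little. The primary granule list's median log2 fold change was then -1.74 (-1.78 with all libraries) and the early erythroid median 1.90 (1.66 with all). A lower share of granulocyte-monocyte progenitors, with every other cell type raised alike, is argued against by megakaryocyte genes. Their median log2 fold change was -1.47 (1 of 9 higher). Falls among them, such as that of Itga2b, were known when the test was chosen. The values thus speak only against this narrow form of the explanation. The lymphoid list fell too (-1.84, 3 of 30 higher), but it also fell in Raptor KO and the source of that fall is open, so it adds little here. Other changes in the mix of sorted cells were not tested. More erythroid progenitors in the sorted cells stay open: 13 of 13 early erythroid markers had log2 fold changes above 0.5 (10 called higher), but this count restates the pattern and cannot speak for that source, and sorting for FcγRII/III is meant to exclude such cells. An effect of Tsc2 loss within progenitors stays open as well.

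B-lymphoid genes were lower in both knockouts. The authors' scaling is argued against as the cause. Over both lines and 2 other scalings, the highest median log2 fold change of the lymphoid list was -1.62. Progenitor libraries had totals of 2.15 to 2.49 M, so scaling to a common total could move this median little. With quantile normalization it was -1.67 in the Raptor line and -1.76 in the Tsc2 line. Mature B cells carried into the control sorts stay open: the fall in Cd74 signal was 2.39 times that in Cd79a in the Raptor line and 4.11 times in the Tsc2 line, but H2-Eb1 fell by 128 against 202 for Cd79a in the Raptor line and by 102 against 103 in the Tsc2 line. All 8 markers examined, Cd74, Cd79a, Cd79b and Ms4a1 among them, were lower in both lines, with 4 and 6 called; in the Raptor line the falls of Cd74 (limma adjusted p = 0.181), H2-Aa (0.437), H2-Ab1 (0.164) and H2-Eb1 (0.473) did not pass. A lineage panel that includes B cells would remove them, and fewer lymphoid-primed progenitors in either knockout were not tested.

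Rapamycin and SL0101 moved 598 genes the same way against shared DMSO libraries. With a different DMSO library for each inhibitor the covariance of log2 fold changes was 0.202 and 0.212 (0.288 with both shared), which argues against the shared libraries as the whole cause. A common effect of both compounds on differentiation stays open, and so do effects of the compounds on targets other than mTORC1 and RSK, which were not tested.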

How the results depend on the processing

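The settings named sex term, male libraries left out, voom and common total were chosen after seeing the data, the last except for Rptor and Tsc2, where it was planned. Without an expression trend limma called 188 genes in Raptor KO, 827 in Tsc2 KO, 599 for the difference, 171 with rapamycin, 87 with SL0101 and 0 between rapamycin and SL0101. Fitting only the groups compared gave 1249 in Raptor KO, 471 in Tsc2 KO and 542 between the inhibitors, and a sex term 838 in Raptor KO. With the replicate number as a replicate block, 1691 genes differed between the inhibitors, while the other counts stayed within 1.5 times. Fits of only the compared groups have fewer libraries and take the spread from those groups alone, while the 4-group fit pools it over both lines. Fewer libraries alone would not raise the Raptor KO count. Which knockout called more genes thus depended on the libraries that gave the spread (522 and 1638 genes in the 4-group fit). No Raptor library was male, so the sex term left the Raptor fold changes as they were and could change only the spread. The cause was otherwise not tested. With an estimated correlation camera called 0 of 19 lists in Raptor KO, 1 of 19 in Tsc2 KO, 1 of 21 for the difference, and 0 of 15, 0 of 12 and 0 of 8 for rapamycin, SL0101 and both compared; the calls that held were the stem and early progenitor list in Tsc2 KO and in the difference. At an adjusted p below 0.1, Raptor KO and rapamycin shared 152 genes in direction (67 at 0.05). Leaving out 1 library gave 146 to 402 genes in Raptor KO, 601 to 2498 in Tsc2 KO, 897 to 2519 for the difference, 540 to 1164 with rapamycin, 323 to 868 with SL0101 and 128 to 863 between the inhibitors. In the Hoxb8 fits this leaves 1 library in a group, which is assumed to vary like the other groups. Rptor in the Tsc2 line, not called, ranged from -0.24 to 0.10 and changed sign without Tsc2 fl/fl replicate 2 (0.10) and without Tsc2 KO replicate 3 (0.10). Rptor in Raptor KO stayed between -0.48 and -0.36 and Tsc2 in Tsc2 KO between -1.44 and -1.28. Scaling to a common total moved the genes between the inhibitors to 440 higher and 699 lower in rapamycin, and voom those in Raptor KO to 250 each (202 and 320 without). Among single genes followed through the settings, 46 lost their call without an expression trend, 5 with only the groups compared and 2 with voom. Without the trend these were Gmnn, Lig1, Myc, Hmgcs1 and Rplp0 in Raptor KO, Insig1, Fen1, Atp5b and Srebf1 in Tsc2 KO, Tsc2 in the difference, Ctsg, Myb, Cx3cr1, Dusp6, Npm1, Cdk6, Kit, Chil1, Nusap1, Cybb, Hmgcs1, Psat1, Plk1 and Ccna2 with rapamycin, Mmp8, Rrs1, Nop58, Mpo, Elane, Mcm2, Ltf, Insig1 and Slc1a5 with SL0101, and all 13 called genes followed between the inhibitors. With only the groups compared the lost calls were Alas1, Car2, Insig1, Srebf1 and Fen1, all in Tsc2 KO. Quantile normalization, the filters and a pseudocount of 0.1 kept all 6 gene counts within 1.5 times. At this depth 2-fold changes were recovered in 47.5% and 53% of simulated cases, all in genes well above 0. Smaller changes, and changes of weakly expressed genes, can thus be missed.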

Other observations

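The test of Tsc2 KO against rapamycin was chosen only after the result was seen. Tsc2 holds mTORC1 inactive and rapamycin inhibits it, so shared genes might move in opposite directions even though the cells differ. Of 302 genes called in both (168 by chance), 215 moved in opposite directions, 114 higher in Tsc2 KO and lower with rapamycin and 101 the reverse, and 87 moved the same way (Fisher's exact p = 9.9e-16). Across the 11334 genes tested in both, fold changes had a Pearson r of -0.103. Genes are not independent replicates, so this p overstates the evidence. Raptor KO is also meant to lower mTORC1 activity, yet its directions were not associated with those in Tsc2 KO (Fisher's exact p = 0.343). Tsc2 KO was not compared with SL0101. The directions in Tsc2 KO and with rapamycin were thus mostly opposite among genes that both settings change, in progenitors and in a line that differ in more than the treatment.

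The fl/fl controls of both lines differed from each other for 80 of 13237 genes (limma), 16 higher and 64 lower in Raptor fl/fl. C1qb (3.37) and Pf4 were among the higher and Spi1 (-1.05) among the lower, so the knockout changes of these 3 genes start from unlike control levels. Further lists passed in camera. In Tsc2 KO they included p53 and cell death genes (5 of 24 higher, 2 lower; 8 and 2 adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.147 with an estimated correlation) and dendritic cell genes (1 of 21 higher, 6 lower; 1 and 9 adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.182 with an estimated correlation). Basophil and mast cell genes passed in Raptor KO (1 of 26 higher; 2 adjusted over the list alone; camera adjusted p = 0.0012; adjusted p = 0.368 with an estimated correlation). In Tsc2 KO that list passed too (6 of 26 higher, 1 lower; 10 and 3 adjusted over the list alone; camera adjusted p = 0.0108; adjusted p = 0.498 with an estimated correlation). That call was lost without Tsc2 fl/fl replicate 2 (adjusted p = 0.105), Tsc2 fl/fl replicate 3 (0.131) or Tsc2 KO replicate 1 (0.444), and without both male libraries (0.101). It passed with rapamycin (2 of 13 higher, also adjusted over the list alone; camera adjusted p = 0.0037; adjusted p = 0.382 with an estimated correlation), but not without rapamycin replicate 2 (0.0545).

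Ribosome biogenesis and Myc target genes were called higher as a list in Tsc2 KO, where Myc itself fell: 1 of 44 rose and 1 fell (0 and 1 adjusted over the list alone; median log2 fold change 0.19; camera adjusted p = 0.0053; adjusted p = 0.425 with an estimated correlation). That call was lost without Tsc2 fl/fl replicate 1 (0.0509) and under quantile normalization (0.358). Reactive oxygen genes (4 of 25 fell; 6 adjusted over the list alone; camera adjusted p = 0.0027) and pentose phosphate genes (1 of 7 fell; 3 adjusted over the list alone; 0.002) were lower in Raptor KO, both at adjusted p = 0.221 with an estimated correlation. The list of mTORC1 pathway components did not pass in Raptor KO (1 of 36 lower, also adjusted over the list alone; camera adjusted p = 0.454) or in Tsc2 KO (4 of 36 higher and 1 lower, also adjusted over the list alone; 0.424).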
